A study of Mus musculus with 9 samples.

How the data were processed

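The series measured gene expression by RNA sequencing in 9 whole-heart samples from mouse pups on postnatal day 1 (P1). The labels place 3 libraries in each of 3 genotypes: wild type (WT), a knockout of Cd36 in the whole body (CD36KO) and a cardiac specific knockout of Cd36 (CD36CKO). Cd36 encodes a membrane protein that takes up long-chain fatty acids. The labels number the replicates within a genotype but do not say whether each came from a separate animal, so the p-values measure only the spread between these libraries, which may be technical in part or, in WT, wholly. In CD36KO and CD36CKO replicate 3 expressed the Y-linked gene Ddx3y (9.72 and 6.19 FPKM). Replicates 1 and 2 of these groups held at most 0.0820 FPKM, so the 3 replicates of neither group all came from the same animal. Strain, litter and sex are not given in the sources used here. RNA was extracted with a column kit, messenger RNA was captured through its poly-A tail, cDNA was primed with random hexamers, and directional libraries were made with dUTP, per the labels' protocols.

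The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to library size) for 56748 genes, with an identifier, symbol, biotype, position, strand and gene length for each, per the file headers. CASAVA, HISAT2, HISAT and TopHat2 are named without versions or roles, per the submitters' processing notes. The read counter, the genome build, the annotation and whether counting used the strand are not given in the sources used here. Positions are therefore printed as the deposited table gives them, with the build not stated.

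FPKM divides by gene length and library size, so a class of transcripts that takes more of the reads lowers all others. Multiplying each FPKM value by gene length gave whole multiples of a fixed step in each library: 100% of the values lay within 0.05 reads of a whole number. The reads recovered in this way were 19316000, 18135000 and 16556000 in WT 1 to 3, 19884000, 14409000 and 16636000 in CD36KO 1 to 3, and 19504000, 20725000 and 15156000 in CD36CKO 1 to 3. The authors' denominators, as the step gives them, were 0.986 to 1.13 times these totals. A count of 0 allows up to 3 reads, which is 0.128 to 0.192 FPKM for a gene of 1 kb, and this limit covers counting error only.

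Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 12206 genes with a mean FPKM of at least 1 over all 9 libraries, 10803 of them protein coding. All 9 libraries entered a single fit with a mean per genotype (6 residual degrees of freedom, and 3.68 added by the empirical Bayes step with a trend on mean expression). The contrasts were CD36KO minus WT, CD36CKO minus WT, CD36KO minus CD36CKO, the mean of both knockouts minus WT, and a moderated F over any genotype. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes.

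Gene lists were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists of each contrast. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and does not compare a list with other genes. Of 44 lists, 37 had at least 3 tested members and were tested. They covered the genes that the study's own text names on these samples (the study axis), G1/S genes, G2/M genes, cell-cycle brakes, retinoid metabolism, fatty acid uptake, fatty acid oxidation, PPAR targets, PPAR coregulators, glycolysis, nuclear-encoded oxidative phosphorylation, the mitochondrial genome, the TCA cycle, lipid synthesis, cardiomyocyte sarcomere, fetal isoforms, atrial, ventricular, growth and regeneration, endothelial, endocardial, fibroblast, mural, epicardial, macrophage, neutrophil, erythroid, liver, skeletal muscle, immediate early, hypoxia, heat shock, integrated stress, interferon, ribosomal protein, extracellular matrix, and neighbours of Cd36 with genes that differ between mouse substrains. The lymphoid (0 tested members), platelet (2), neural (2), adipose (2), lung (1), female (1) and male (2) lists had too few tested members. The glycolysis list has 29 tested entries because the table holds 2 genes with the symbol Aldoa.

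The genotypes, tests, lists and the rule for named genes were fixed before the data were examined. The rule named Cd36, the study axis, and for each knockout against WT the 6 protein-coding genes with the largest change in each direction among those past the threshold whose libraries did not overlap between the groups. Chance alone separates 3 libraries from 3 in 10% of genes. It added the 3 members with the smallest p from each of 7 primary lists (G1/S, G2/M, brakes, retinoid, uptake, oxidation and PPAR targets). From every other list with an adjusted camera p under 0.05 or at least 3 members past the threshold, it took 2 members with the smallest p. For CD36KO minus CD36CKO and for both knockouts it took Cd36 and the 4 largest in each direction. Not every gene that the rule names is printed. A gene outside the rule is said to have been chosen after its values were seen. Of 116 genes named by the rule, 23 overlap another gene with a mean FPKM of at least 1, 18 of them on the opposite strand, so their values are uncertain. The same holds for genes with near-identical copies or pseudogenes, such as the haemoglobins, ribosomal proteins, Gapdh, Eno1 and the mitochondrial genes.

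Other settings fixed at the same time were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5, median-ratio scaling, quantile normalization, removal of mitochondrially encoded and haemoglobin genes with rescaling, no trend, library weights, the replicate number as a block, only the groups compared, a log2 fold change of at least 1, an adjusted p of 0.1, and each library left out in turn. The removal setting made the sum of the remaining FPKM equal in every library, and the filter was applied to the rescaled values. It therefore also replaced scaling by reads with scaling by summed FPKM. Its shifts cannot be credited to the removed genes alone, here and wherever these genes are said to be removed. Chosen after seeing the data were limma's voom on the recovered reads, the mean of the atrial list as a covariate, removal of a trend with gene length, and a fit without the 2 libraries with Y-linked expression. The default estimate of library weights did not converge, so limma's gene-by-gene estimate was used in its place, a change also made after seeing the data.

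The script was tested on simulated data for CD36KO against WT over 12206 genes, with 200 genes changed and a further list of 40 genes shifted by 0.5. Genes were drawn independently with the same spread in every group, unlike the real libraries, so its rates may not hold for them. It recovered 17.9% of genes changed by 0.5 on the log2 scale, 85.1% at 1 and 95.5% at 2, and 6 of its 145 calls (4.14%) were genes without a simulated change. No pair of replicates looked like the same library deposited again: the chi-square of their recovered reads per degree of freedom was 14.4 to 100. Every value column of the deposited table was used, and single-gene results for non-coding and unnamed genes were left out except where stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.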

Results

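Whole-heart RNA was profiled on postnatal day 1 in 9 mouse libraries, 3 from wild-type (WT) pups, 3 from pups labelled as lacking Cd36 in the whole body (CD36KO) and 3 labelled as lacking it in the heart (CD36CKO). Between 14409000 and 20725000 reads per library lay behind the FPKM values, and 12206 genes were expressed highly enough to test. A principal component analysis of the log values separated WT from both other groups along its first axis, which held 34.3% of the variance, and CD36KO from the libraries labelled CD36CKO along the second (22.7%). Replicates correlated at 0.958 to 0.987 in WT, 0.984 to 0.986 in CD36KO and 0.972 to 0.983 in the libraries labelled CD36CKO, and the median SD of a gene was 0.21, 0.11 and 0.14 on the log2 scale. Mitochondrially encoded transcripts took 6.02%, 4.55% and 8.89% of the reads in WT 1 to 3, 11.9%, 11.1% and 14.3% in CD36KO and 10.3%, 10.3% and 12.2% in the libraries labelled CD36CKO. Y-linked transcripts were expressed in 2 libraries, CD36KO 3 and CD36CKO 3, and the other 7 had levels of Xist from 12.3 to 25.8 FPKM. CD36CKO 3 also carried transcripts of skeletal muscle: the 14 genes of that list summed to 1494 FPKM there and to between 6.31 and 18 FPKM in every other library. FDR is the adjusted p from limma for a gene, or from camera for a list, with 3 libraries per group. Where 5 or fewer members of a list passed the threshold, those introduced by "also" lie outside the rule for named genes and were chosen after their values were seen.

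Cd36 (ENSMUSG00000002944, chromosome 5, 17986688 to 18093799 on the minus strand, build not given), which encodes a fatty acid translocase, was measured first as a check of the labels. Its level was 163, 150 and 125 FPKM in WT 1 to 3 (mean 146 ± 19.4, SD, n = 3) and 72.4, 64.0 and 60.6 FPKM in CD36KO 1 to 3 (65.7 ± 6.05, n = 3). The CD36KO mean was 45.0% of WT, a log2 fold change of -1.14 (SE 0.14, FDR = 0.00345 from limma). The libraries labelled CD36CKO held 201, 183 and 163 FPKM (183 ± 18.8, n = 3), 125% of the WT mean, with a log2 fold change of 0.32 (SE 0.14, FDR = 0.153 from limma). This level does not bear out the label, but it cannot contradict it alone. It is a value of the whole gene in the whole heart, in which other cells also express Cd36 and in which a deleted exon cannot be seen. CD36KO, labelled as lacking Cd36 in the whole body, also kept 45.0% of the WT level. With mitochondrial and haemoglobin genes removed the same contrast was 0.60 (FDR = 0.0177) and with quantile normalization 0.67 (FDR = 0.0139), both past the threshold. These libraries are called the libraries labelled CD36CKO, the word knockouts for both groups follows the labels alone, and every direction drawn from them rests on a label that the Cd36 level does not bear out.

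**Figure D1:**
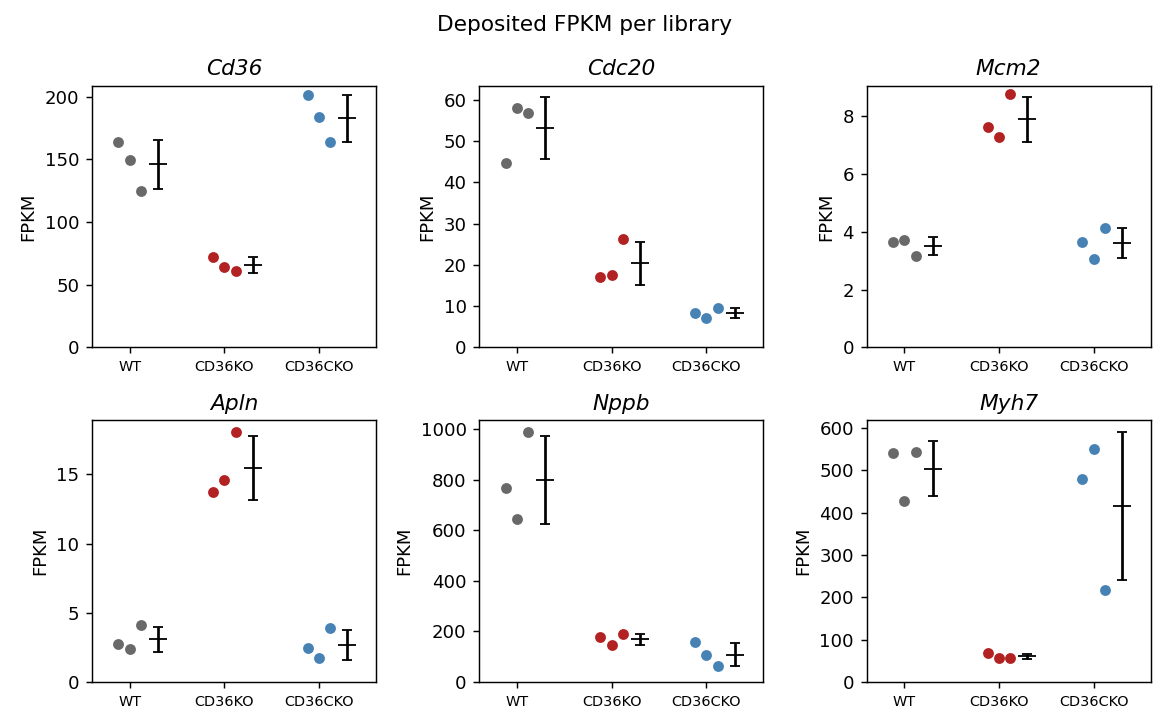
FPKM per library for Cd36, Cdc20, Mcm2, Apln, Nppb and Myh7 in WT, CD36KO and the libraries labelled CD36CKO; points are libraries and bars show the mean ± SD of 3 libraries. Cd36 lay between 60.6 and 72.4 FPKM in CD36KO and between 163 and 201 in the libraries labelled CD36CKO, against 125 to 163 in WT.

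The comparison of CD36KO with WT asked which heart transcripts differ on the first day after birth when Cd36 is disrupted in all tissues. Apln, the ligand of the apelin receptor, rose from 3.08 ± 0.889 FPKM in WT to 15.5 ± 2.31 in CD36KO (SD, n = 3), a log2 fold change of 2.03 (SE 0.22, FDR = 0.00247). Myh7, the slow beta-myosin heavy chain of the fetal heart, fell from 504 ± 65.5 to 60.1 ± 6.47 FPKM (-3.04, SE 0.30, FDR = 0.00219). Among the other genes with the largest rises were mt-Co3 (2.42), Asb14 (1.87), mt-Atp6 (1.82) and Scgb1c1 (1.81), and those with the largest falls were the atrial transcripts Myl7 (-4.66), Sln (-4.42), Myl4 (-4.11) and Nppa (-3.29), and Uts2b (-2.88), with an FDR from 0.00219 for Asb14 to 0.0475 for mt-Atp6. Calls were lost in 14 of 22 other settings for mt-Atp6, 13 of 23 for Sln, 7 of 22 for mt-Co3 and 6 of 23 for Myl7. Sln was at 57.1 FPKM in CD36KO 2, against 1.34 in CD36KO 1 and 1.32 in CD36KO 3. Uts2b had 0 reads in CD36KO 1 and CD36KO 3. In all, 709 genes were higher and 818 lower, 1527 of the genes tested, and 55 and 138 of them differed by a log2 fold change of at least 1. In 2 fits chosen after seeing the data, 200 genes passed without the 2 libraries with Y-linked expression, and with an atrial score as a covariate limma called 0, with 751 at an unadjusted p under 0.05. With mitochondrial and haemoglobin genes removed and the libraries rescaled to the same FPKM sum, 637 were higher and 304 lower, and the median of all genes moved to 0.12.

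Genes of DNA replication and of mitosis moved apart in CD36KO. Of 43 tested G1/S genes, 15 rose and none fell (25 rose when adjusted over the list alone), with a median log2 fold change of 0.45 (camera FDR = 1.15e-11; adjusted p = 0.333 with an estimated correlation). Mcm4 (1.08, SE 0.11, FDR = 0.00224) and Mcm2 (0.98, SE 0.12, FDR = 0.00283) encode subunits of the replicative helicase, and Ccnd1 (0.93, SE 0.12, FDR = 0.00323) encodes cyclin D1. Of 60 G2/M genes, 25 fell and none rose (35 fell adjusted over the list alone), with a median of -0.60 (camera FDR = 6.02e-14; adjusted p = 0.502 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 53.2 ± 7.50 to 20.4 ± 5.2 FPKM (-1.36, FDR = 0.00450). Ube2c, its ubiquitin-conjugating enzyme, fell by a log2 fold change of -1.38 (FDR = 0.00475), and the spindle protein gene Tacc3 by -1.10 (FDR = 0.00556). Among 20 cell-cycle brakes, Rbl1, of the retinoblastoma family, rose (0.76, FDR = 0.0210), whereas Cdkn2d, an inhibitor of CDK4 and CDK6, fell (-0.99, FDR = 0.00586) and so did Gadd45g (-0.81, FDR = 0.0337). The list as a whole did not pass (median 0.16, camera FDR = 0.298), with 1 higher and 2 lower also when adjusted over the list alone. Medians of both cycle lists kept their sign in every refit, but their counts did not hold. The 25 falls among G2/M genes were 8, 9 and 16 without CD36KO 1, 2 or 3, 8 with mitochondrial and haemoglobin genes removed, 10 with no filter, and 11 without the libraries with Y-linked expression, and library weights gave a median of -0.39. The 15 rises among G1/S genes were 9, 7 and 6 without CD36KO 1, 2 or 3, 7 without WT 1, 36 with library weights and 5 without the libraries with Y-linked expression. With the atrial covariate 0 members of either list passed, at medians of -0.50 (G2/M) and 0.47 (G1/S), while the median SE of the G2/M genes rose from 0.20 to 0.44. Cdc20, Tacc3 and Ccnd1 overlap a gene on the opposite strand, so their values are uncertain.

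The study's own axis did not pass as a list in CD36KO (5 genes, median -0.17, mean 0.01, camera FDR = 0.656), and since the study chose it on these samples it is not independent evidence. Over all genes 0 members passed, with 1 higher and 2 lower when adjusted over the list alone. Fabp5, a fatty acid binding protein, was at -0.51 (SE 0.16, FDR = 0.0606) and the nuclear receptor gene Ppard at -0.17 (FDR = 0.416). Of the retinoid X receptor genes, Rxrb was at -0.30 (FDR = 0.117), Rxra at 0.13 (FDR = 0.410) and Rxrg at 0.92 (FDR = 0.0723). In the retinoid list (16 genes, median 0.11, camera FDR = 0.644), Aldh1a2, which makes retinoic acid, rose (1.40, SE 0.17, FDR = 0.00330), while the receptor gene Rara fell (-0.42, FDR = 0.0485), a call lost without any one library other than WT 3. Adjusted over the list alone 2 rose and 2 fell. Of 22 fatty acid uptake genes (median 0.03, camera FDR = 0.273), Meox2, a transcription factor of the endothelium (1.14, SE 0.11, FDR = 0.00219), and Vldlr, a lipoprotein receptor (0.42, FDR = 0.0333), rose, and Acsl1, an acyl-CoA synthetase, was at 0.58 (FDR = 0.0505). Adjusted over the list alone 4 rose and 1 fell.

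Fatty acid oxidation genes lay higher and glycolysis genes lower in CD36KO. Of 30 oxidation genes, 4 rose and none fell (9 rose adjusted over the list alone), with a median of 0.36 (camera FDR = 0.000334; adjusted p = 0.641 with an estimated correlation). They were Acadm (0.62, FDR = 0.0225), the enoyl-CoA handling enzymes Ech1 (1.17, FDR = 0.0258) and Decr1 (1.0, FDR = 0.0291), and also Acad11 (0.54). Of 29 glycolysis entries, 1 rose and 10 fell (1 and 13 adjusted over the list alone), with a median of -0.40 (camera FDR = 0.00190; adjusted p = 0.333 with an estimated correlation). Enolase gene Eno1 fell from 206 ± 27.4 to 83.7 ± 3.59 FPKM (-1.28, SE 0.13, FDR = 0.00224) and the phosphofructokinase gene Pfkp by a log2 fold change of -0.85 (FDR = 0.00492). The 13 protein-coding genes of the mitochondrial genome had a median of 1.08, and 8 rose (10 adjusted over the list alone; camera FDR = 1.80e-06; adjusted p = 0.333 with an estimated correlation), among them mt-Nd4l (1.43) and mt-Nd4 (1.08), whose transcripts overlap each other. PPAR targets did not pass as a list (27 genes, median 0.18, camera FDR = 0.0708). Over all genes and over the list alone 1 member was higher and 1 lower, Pnpla2, a triglyceride lipase (-0.46, FDR = 0.0361), and Fabp3 was at 1.10 (FDR = 0.0671). The PPAR targets passed in CD36KO in 7 of 25 other settings, among them quantile normalization (median 0.23, FDR = 0.0135). Without WT 3 the oxidation median was 0.18, and with library weights 0.15. By fry the oxidation list did not pass (adjusted p = 0.14). The glycolysis median was -0.23 without WT 2, -0.18 with quantile normalization and -0.25 with mitochondrial and haemoglobin genes removed.

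None of the lists of PPAR coregulators (20 genes, 0 past the threshold, camera FDR = 0.790), nuclear-encoded oxidative phosphorylation (49 genes, 0 past it, FDR = 0.686), TCA cycle (16 genes, FDR = 0.434) and lipid synthesis (25 genes, FDR = 0.174) passed in CD36KO, and their medians lay between -0.02 and 0.19. The oxidative phosphorylation genes had a median of -0.02 and a mean of 0.01. In the TCA list also Dld rose (0.54) and also Pcx fell (-0.74). In lipid synthesis Gpam (0.73), Elovl5 (0.62) and also Fasn (0.36) rose. The counts of these 4 lists were the same when adjusted over the list alone.

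Atrial transcripts were lower in CD36KO than in WT. Of 11 atrial genes 9 fell and none rose (10 fell adjusted over the list alone), with a median of -1.84 (camera FDR = 6.92e-07; adjusted p = 0.333 with an estimated correlation). Nppa, which encodes atrial natriuretic peptide, fell from 2242 ± 629 to 253 ± 154 FPKM (SD, n = 3), and Bmp10, an atrial growth factor, by a log2 fold change of -2.69 (FDR = 0.00737). The mean log2 level of the list was 5.78, 6.23 and 6.39 in WT 1 to 3, 3.34, 4.87 and 3.33 in CD36KO, and 5.19, 4.37 and 4.35 in the libraries labelled CD36CKO. Of 18 fetal isoforms, 6 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.50; camera FDR = 0.00120; adjusted p = 0.333 with an estimated correlation). They included Myh7 and Nppb, the gene of B-type natriuretic peptide, which fell from 801 ± 174 to 170 ± 21.9 FPKM (-2.22, FDR = 0.00460), and 3 members of the atrial list. Their median was -1.25 with a mean of at least 5 FPKM and -0.30 with the atrial covariate, which shares these 3 genes. Neither the sarcomere list (32 genes, 4 higher and 3 lower, 6 and 4 adjusted over the list alone, camera FDR = 0.298) nor the ventricular list (7 genes, 2 higher, FDR = 0.0708) passed. In them Pln, the inhibitor of the sarcoplasmic calcium pump (1.24, FDR = 0.00224), Gja1 (0.73) and also Irx4 (0.38) rose. The growth and regeneration list had a median of 0.12 and a mean of -0.01 (25 genes, camera FDR = 0.558). In it Erbb2, a neuregulin receptor gene, fell (-0.91, SE 0.10, FDR = 0.00257) and Mycn (0.81), also Fgf1 (0.54) and also Hif1a (0.50) rose. Myh7, Myl4, Nppa, Pln and Erbb2 overlap other genes on the opposite strand and are uncertain.

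Markers of other cells moved in both directions in CD36KO, and of their lists the erythroid one alone passed. In the endothelial list (20 genes, median 0.09, camera FDR = 0.373) Kdr (0.58) and also Cldn5 (0.84) rose, and Eng (-0.63) and also Tie1 (-0.47) fell. In the endocardial list (5 genes, FDR = 0.288) also Npr3 (-0.84) and also Plvap (-0.81) fell, with 3 lower adjusted over the list alone. In the fibroblast list (16 genes, median -0.17, FDR = 0.383) Dpep1 (-1.42), Gsn (-0.62) and also Fbln2 (-0.43) fell and also Dcn rose (0.55). In the mural list (11 genes, median 0.21, FDR = 0.0656) the pericyte gene Rgs5 (1.19, FDR = 0.00219), and also Abcc9 (1.18), also Vtn (0.97) and also Rgs4 (0.63) rose, while the smooth muscle gene Cnn1 fell (-2.24, FDR = 0.00254). In the epicardial list (10 genes, median -0.63, FDR = 0.0656) the keratin gene Krt19 fell from 11.6 ± 0.649 to 2.45 ± 0.406 FPKM (-1.87, SE 0.12, FDR = 0.000237). Also Krt8 (-0.77) and also Upk1b (-0.77) fell, while Aldh1a2, a member of this list too, rose. In the macrophage list (11 genes, FDR = 0.373) also Cx3cr1 (0.92) and also Adgre1 (0.59) rose, and in the neutrophil list (5 genes, FDR = 0.0604) also S100a9 (-0.98) and also Retnlg (-0.87) fell. The erythroid list had a median of -0.56 with 0 of 8 genes past the threshold over all genes and 5 lower adjusted over the list alone (camera FDR = 0.0241; adjusted p = 0.476 with an estimated correlation). Hbb-bt was at -0.88 (FDR = 0.0576) and Hba-a1 at -0.95 (FDR = 0.0759), and both have near-identical copies. The liver (6 genes, FDR = 0.493) and skeletal muscle lists (9 genes, FDR = 0.644) had 0 members past the threshold.

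Interferon-stimulated genes were lower in CD36KO. Of 12 tested, 8 fell and none rose, also adjusted over the list alone, with a median of -0.79 (camera FDR = 5.89e-06; adjusted p = 0.333 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, fell from 22.1 ± 4.75 to 5.73 ± 1.69 FPKM (-1.79, SE 0.21, FDR = 0.00283), and Oasl2 by a log2 fold change of -1.07 (FDR = 0.00433). Of 14 integrated stress genes, 4 fell (5 adjusted over the list alone; median -0.25; camera FDR = 0.0130; adjusted p = 0.333 with an estimated correlation). They were the serine synthesis gene Phgdh (-1.14, FDR = 0.00254), Shmt2 (-0.74, FDR = 0.00475), and also Mthfd2 (-0.63) and also Psat1 (-0.58). The ribosomal protein list lay lower as a group with 0 of 33 members past the threshold (0 adjusted over the list alone; median -0.37; camera FDR = 1.20e-05; adjusted p = 0.661 with an estimated correlation). Rps19 was at -0.52 (FDR = 0.0752) and Rpl13 at -0.58 (FDR = 0.0767). The hypoxia list missed the threshold (15 genes, median -0.38, FDR = 0.0573), with Mt2 (-1.55), Ddit4 (-0.97) and also Mt1 (-0.59) lower. Likewise the immediate early (20 genes, FDR = 0.434), heat shock (13 genes, FDR = 0.144) and extracellular matrix lists (28 genes, FDR = 0.612) did not pass. Their members past the threshold were Dusp1 (0.63), Gadd45b (-0.77) and also Klf4 (0.82), also Hspb1 (-1.04) and also Cryab (-0.70), and also Col15a1 (0.73) and also Col6a2 (-0.40). Of 10 tested neighbours of Cd36 and substrain genes, 3 rose (3 adjusted over the list alone; median 0.38; camera FDR = 0.00936; adjusted p = 0.333 with an estimated correlation): Sema3c (0.75), Gnai1 (0.53) and also Phtf2 (0.51). Library weights ended the calls of the fatty acid oxidation, erythroid, integrated stress and Cd36 neighbour lists, and the atrial covariate those of the erythroid and Cd36 neighbour lists. The erythroid call was also lost without CD36KO 1 (FDR = 0.0575) and with haemoglobin genes removed. The ribosomal median was -0.22 without WT 2, -0.17 with quantile normalization and -0.23 with mitochondrial and haemoglobin genes removed, and the list did not pass by fry (adjusted p = 0.13). The filter moved the interferon median to -0.49 (none) and -1.30 (at least 5 FPKM), and the integrated stress median to -0.46 (at least 5 FPKM). The Cd36 neighbours were at 0.11 with no filter and 0.23 without WT 2.

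The libraries labelled CD36CKO were compared with WT to ask what differs when the deletion is meant to be limited to the heart. Ucp3, a mitochondrial carrier of muscle, rose from 5.44 ± 3.79 FPKM in WT to 23.5 ± 5.61 (SD, n = 3; log2 fold change 2.15, SE 0.46, FDR = 0.0205), and Fbp2 (1.58), Slc25a34 (1.49), Tmem82 (1.45) and Asb14 (1.43) were among the largest rises. Fbp2 lost its call in 14 of 23 other settings, Ucp3 and Slc25a34 in 6 of 23 each, Tmem82 in 1 of 22 and Asb14 in 1 of 23. Nppb fell from 801 ± 174 to 108 ± 47.0 FPKM (-2.95, SE 0.30, FDR = 0.000962), Myl4 by a log2 fold change of -2.97 (FDR = 0.0250) and Uts2b by -2.96 (FDR = 0.00458). Cdc20, Ube2c and Cdca3, all genes of mitosis, had the other largest falls (-2.53, -2.53 and -2.51, FDR = 0.000306 for each). The WT contrast held 654 genes higher and 893 lower, 1547 in all, of which 50 and 209 differed by a log2 fold change of at least 1. Without the 2 libraries with Y-linked expression 412 genes passed, with the atrial score as a covariate 13, and without CD36CKO 3, which carried skeletal muscle transcripts, 947. With mitochondrial and haemoglobin genes removed and the libraries rescaled to the same FPKM sum, 1410 were higher and 375 lower. The median of all genes then moved to 0.25, a shift that the change of scaling can give too. The whole-gene Cd36 level of these libraries does not bear out their label.

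Mitotic genes fell almost without exception in the libraries labelled CD36CKO. Of 60 G2/M genes 59 fell (60 adjusted over the list alone), with a median of -1.52 (camera FDR = 2.36e-44; adjusted p = 0.372 with an estimated correlation); also Smc2 was at -0.65 (FDR = 0.0868). With a mean of at least 5 FPKM 30 of 30 tested members fell (median -1.86). With the atrial covariate 7 fell, at a median of -1.46, while the median SE of these genes rose from 0.20 to 0.33. Cdc20 fell from 53.2 ± 7.50 to 8.35 ± 1.26 FPKM (SE of the log2 fold change 0.18), Ube2c from 46.9 ± 8.68 to 7.33 ± 1.56 FPKM. The chromosome-associated kinesin gene Kif4 fell from 5.44 ± 0.781 to 0.837 ± 0.169 FPKM (-1.81, SE 0.13, FDR = 0.000306). G1/S genes leaned lower, with 5 of 43 down and 2 up (10 and 2 adjusted over the list alone; median -0.28; camera FDR = 0.0254; adjusted p = 0.680 with an estimated correlation). The members that fell were the subunits of ribonucleotide reductase Rrm2 (-1.34, SE 0.26, FDR = 0.0140) and Rrm1 (-0.64, FDR = 0.0169), the thymidine kinase gene Tk1 (-0.95, FDR = 0.0205), and also Lig1 (-0.66) and also Cdc45 (-0.52). Also Ccnd2 (0.48) and also Slbp (0.44) rose. The list call was lost without WT 2 (FDR = 0.0529), WT 3 (FDR = 0.0700), CD36CKO 1 (FDR = 0.0550) or CD36CKO 2 (FDR = 0.147). With mitochondrial and haemoglobin genes removed the G1/S median was -0.08, with 3 members higher and 1 lower. Of 20 cell-cycle brakes 3 rose and 4 fell (5 and 4 adjusted over the list alone; median 0.21; camera FDR = 0.286). The fallen brakes were Cdkn2d (-1.48, FDR = 0.000849), Cdkn2c (-0.98, FDR = 0.00348), both inhibitors of CDK4 and CDK6, Gadd45g (-1.34, FDR = 0.00563) and also Cdkn1a (-0.87). Those that rose were also Tob1 (0.67), also Meis1 (0.51) and also Rb1 (0.50). Cdc20, Kif4 and Tk1 overlap a gene on the opposite strand and are uncertain.

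**Figure D2:**
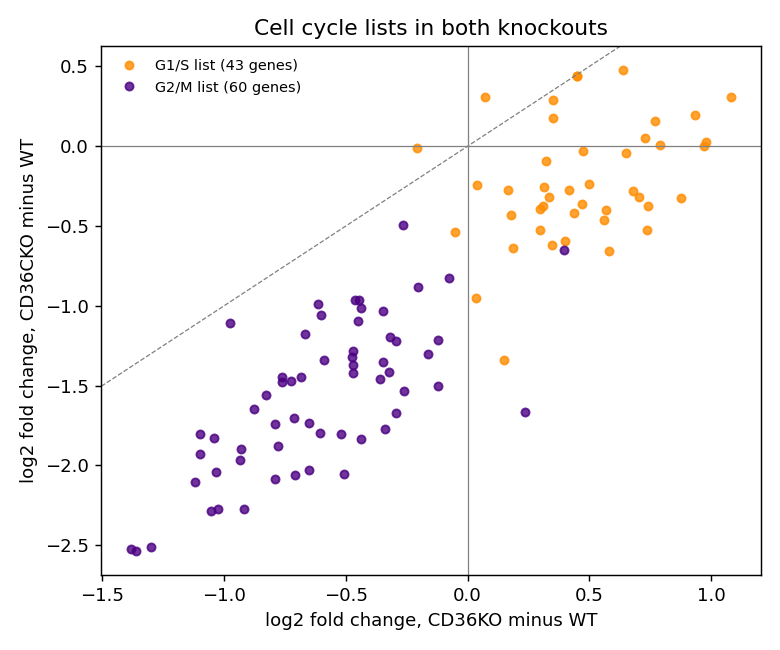
Log2 fold change of each G1/S gene (43) and G2/M gene (60) in CD36KO against WT (x axis) and in the libraries labelled CD36CKO against WT (y axis), with a dashed line where both are equal. The G2/M genes had a median of -0.60 on the x axis and -1.52 on the y axis, and the G1/S genes 0.45 and -0.28.

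Within the study's axis, Fabp5 fell in the libraries labelled CD36CKO from 70.5 ± 5.70 to 40.8 ± 5.75 FPKM (-0.78, SE 0.16, FDR = 0.0161). Ppard was at -0.02 (FDR = 0.945), Rxrb at -0.16 (FDR = 0.351), Rxra at -0.09 (FDR = 0.556) and Rxrg at 0.34 (FDR = 0.453). As a list it did not pass (1 of 5 lower, also adjusted over the list alone; median -0.09; camera FDR = 0.371), and the study chose it on these samples, so it is not independent evidence. With mitochondrial and haemoglobin genes removed Fabp5 was at -0.51 (FDR = 0.0575) and the list median at 0.18. The Fabp5 call was also lost without WT 2 (FDR = 0.0503) and without CD36CKO 2. In the retinoid list (16 genes, median 0.23, camera FDR = 0.136), the receptor gene Rarg rose (0.52, FDR = 0.0137), with Rdh13 at 0.47 (FDR = 0.0592). Adjusted over the list alone 4 rose and 1 fell. The fatty acid uptake list did not pass (22 genes, 4 higher and 2 lower, 5 and 4 adjusted over the list alone, camera FDR = 0.354), with Meox2 (0.75, FDR = 0.00535) and Acsl1 (0.85, FDR = 0.0157) higher.

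PPAR targets and fatty acid oxidation genes were higher in the libraries labelled CD36CKO. Of 27 PPAR targets 6 rose and none fell (10 adjusted over the list alone), with a median of 0.51 (camera FDR = 1.29e-05; adjusted p = 0.447 with an estimated correlation). Besides Ucp3 they included Slc25a42, a mitochondrial carrier of coenzyme A (1.05, SE 0.15, FDR = 0.00389), and Cpt1a, the gate of mitochondrial fatty acid entry (0.68, FDR = 0.0203). Of 30 oxidation genes 4 rose (10 adjusted over the list alone; median 0.42; camera FDR = 6.32e-05; adjusted p = 0.521 with an estimated correlation), namely Cpt1a, the carnitine transporter gene Slc22a5 (0.42, FDR = 0.0222), Etfdh (0.74, FDR = 0.0315) and also Hadhb (1.0). Of 29 glycolysis entries 10 fell and 1 rose (12 and 2 adjusted over the list alone; median -0.40; camera FDR = 0.000918; adjusted p = 0.372 with an estimated correlation), with Eno1 at -0.93 (FDR = 0.00458) and Aldoc at -0.73 (FDR = 0.00475). With quantile normalization the list did not pass (median -0.04, FDR = 0.0905). The mitochondrial genome list had a median of 0.84 (3 of 13 higher, 8 adjusted over the list alone; camera FDR = 0.000343; adjusted p = 0.447 with an estimated correlation), from mt-Nd4l (1.00), mt-Nd4 (0.81) and also mt-Cytb (0.84). Nuclear-encoded oxidative phosphorylation genes had a median of -0.32 (2 of 49 lower, 0 adjusted over the list alone; camera FDR = 0.000318; adjusted p = 0.680 with an estimated correlation), with Atp5k (-1.13) and Cox7a1 (-0.80) lower. Cox7a1 lost its call in 15 of 23 other settings and Atp5k in 9 of 23. The median of the oxidative phosphorylation list was 0.06 with quantile normalization, and the list call was lost without WT 2. Lipid synthesis genes, with 4 of 25 higher (4 adjusted over the list alone; median 0.11; camera FDR = 0.0483; adjusted p = 0.447 with an estimated correlation), kept the call in 13 of 25 other settings. The members that rose were Gpam (0.78), Fasn (0.36), also Dgat2 (0.69) and also Hmgcs1 (0.53). PPAR coregulators did not pass (camera FDR = 0.0759), with Nrf1 lower (-0.38) and Ncoa1 (0.34) and also Esrrg (0.45) higher, nor did the TCA list (FDR = 0.837), in which also Pcx fell (-0.65). The oxidation median was 0.21 without WT 3, 0.24 with library weights and 0.73 with quantile normalization. Neither the oxidation list (adjusted p = 0.0963) nor the oxidative phosphorylation list (adjusted p = 0.264) passed by fry. The PPAR target median was 0.77 with quantile normalization, 0.79 with mitochondrial and haemoglobin genes removed and 0.31 with library weights. With the same genes removed the glycolysis, oxidative phosphorylation and lipid synthesis medians were -0.04, -0.04 and 0.37, and oxidative phosphorylation was at -0.14 without WT 2, -0.56 without WT 3 and -0.19 with the length trend removed.

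Atrial, epicardial and extracellular matrix lists were lower in the libraries labelled CD36CKO than in WT. Atrial genes had a median of -1.41 with 4 of 11 lower (7 adjusted over the list alone; camera FDR = 0.00132; adjusted p = 0.499 with an estimated correlation). They were Myl4, Stard10 (-1.27, FDR = 0.0161), and also Bmp10 (-1.57) and also Dkk3 (-1.41). Their call was lost without WT 3 (FDR = 0.0544), with library weights and by fry (adjusted p = 0.0737). In the fetal isoform list (18 genes, median -0.27, camera FDR = 0.0831) Nppb, Myl4, and also Ankrd1 (-2.09) and also Vim (-0.64) fell, and the inward rectifier channel gene Kcnj2 rose (1.23, SE 0.11, FDR = 0.000509). Epicardial genes were lower (4 of 10, 6 adjusted over the list alone; median -0.66; camera FDR = 0.00745; adjusted p = 0.447 with an estimated correlation), led by Krt19 (-1.23, FDR = 0.000849) and Krt8 (-0.69), with also Krt18 (-1.21) and also Upk1b (-0.63). Extracellular matrix genes had a median of -0.27 that became 0.01 with mitochondrial and haemoglobin genes removed (3 of 28 lower, 3 adjusted over the list alone; camera FDR = 0.00537; adjusted p = 0.521 with an estimated correlation), from Col6a2 (-0.54), Lama4 (-0.33) and also Mmp14 (-0.64). Without WT 3 neither the epicardial nor the extracellular matrix call held. Quantile normalization, library weights and fry (adjusted p = 0.113) also ended the matrix call, and a mean of at least 5 FPKM the epicardial one. The sarcomere (FDR = 0.925), ventricular (FDR = 0.432), growth (FDR = 0.840) and endothelial lists (FDR = 0.925) did not pass. Nor did the endocardial (FDR = 0.0545), fibroblast (FDR = 0.0652), mural (FDR = 0.109), macrophage (FDR = 0.351), neutrophil (FDR = 0.0716), erythroid (FDR = 0.354), liver (FDR = 0.0716) and skeletal muscle lists (FDR = 0.15). Named members of these lists past the threshold were Pln (0.72), Gja1 (0.60), Hey2, a ventricular transcription factor gene (1.03, FDR = 0.00935), Mycn (0.73), Erbb2 (-0.43), Sox18 (0.92), Eng (-0.65), Vwf (-0.84), Plvap (-0.90), Fbln2 (-0.58), Gsn (-0.62), Rgs5 (0.82) and Abcc9 (0.94). Outside the rule, also Irx4 (0.50), also Rgcc (0.90), also Tcf21 (0.50) and also Rgs4 (0.56) rose. Also Actn2 (-0.58), also Ccn2 (-1.90), also Gas2l3 (-0.88), also Tie1 (-0.48), also Esam (-0.44), also Npr3 (-0.79), also Fn1 (-0.72), also Dpt (-0.63), also Cnn1 (-0.92), also S100a9 (-1.0) and also S100a8 (-0.84) fell. Medians and means differed in sign for endothelial (-0.03 and 0.05), ventricular (-0.25 and 0.10) and growth genes (0.07 and -0.09), and camera ranked the TCA and sarcomere lists upward although their medians were -0.02 and -0.13.

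Interferon and integrated stress genes were also lower in the libraries labelled CD36CKO. Of 12 interferon genes 6 fell and none rose (8 adjusted over the list alone; median -0.70; camera FDR = 8.57e-06; adjusted p = 0.372 with an estimated correlation). Isg15 fell from 22.1 ± 4.75 to 4.72 ± 0.768 FPKM (-2.0, FDR = 0.00119) and Ifi27l2a from 43.6 ± 13.3 to 8.04 ± 2.15 FPKM (-2.28, FDR = 0.00165). Of 14 integrated stress genes 6 fell, the same number adjusted over the list alone (median -0.39; camera FDR = 0.00132; adjusted p = 0.372 with an estimated correlation), led by Mthfd2 (-1.17, FDR = 0.00136) and Phgdh (-1.14, FDR = 0.00149). Of 33 ribosomal protein genes 8 fell and 25 did so adjusted over the list alone (median -0.56; camera FDR = 1.81e-09; adjusted p = 0.499 with an estimated correlation). Rpl35 was at -0.82 (FDR = 0.0222) and Rpl37 at -0.73 (FDR = 0.0203), and these genes have processed pseudogenes and are uncertain. The Cd36 neighbours and substrain genes had a median of 0.37 (1 of 10 higher, 1 adjusted over the list alone; camera FDR = 0.0170; adjusted p = 0.372 with an estimated correlation), from Gnai1 (0.65, FDR = 0.0132), with Phtf2 at 0.40 (FDR = 0.0645). The call was lost with mitochondrial and haemoglobin genes removed (median 0.62), with library weights (0.24) and with the atrial covariate (0.14), and with no filter the median was 0.07. Immediate early (FDR = 0.717), hypoxia (FDR = 0.840) and heat shock lists (FDR = 0.427) did not pass, with also Atf3 (-1.24) and also Cryab (-0.68) lower and also Vegfa higher (1.05). The interferon median was -1.15 with a pseudocount of 0.1, -1.28 with voom, -0.46 with no filter and -2.0 with at least 5 FPKM. With mitochondrial and haemoglobin genes removed the integrated stress median was -0.20 and the ribosomal median -0.29, and the latter was -0.18 with quantile normalization and -0.35 without WT 2.

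A direct comparison of CD36KO with the libraries labelled CD36CKO tested whether the effects differ. Cell-cycle genes were higher in CD36KO, with none lower in either list. They were 27 of 43 G1/S genes (35 adjusted over the list alone; median 0.74; camera FDR = 3.91e-22; adjusted p = 0.722 with an estimated correlation). They were also 38 of 60 G2/M genes (56 adjusted over the list alone; median 0.98; camera FDR = 2.49e-36; adjusted p = 0.722 with an estimated correlation). These counts rested on single libraries, while the medians held: without CD36KO 3 the G1/S and G2/M counts were 1 and 2, without CD36CKO 2 they were 1 and 6, and without CD36KO 2 they were 12 and 15. They were 7 and 7 without the libraries with Y-linked expression, 14 and 18 with mitochondrial and haemoglobin genes removed, 11 and 13 with no filter and 0 and 2 with the atrial covariate, where the median SE of the G2/M genes rose from 0.20 to 0.25. Apln, at 15.5 ± 2.31 against 2.68 ± 1.11 FPKM (SD, n = 3), differed by a log2 fold change of 2.20 (SE 0.22, FDR = 0.00804). The stress-induced transcription factor gene Atf3 (1.97, FDR = 0.0103), the mitotic kinase gene Pbk (1.90, FDR = 0.00941) and Rps27a (1.72, FDR = 0.0491) were higher in CD36KO. Myh7 was lower in CD36KO, at 60.1 ± 6.47 against 416 ± 176 FPKM (-2.67, SE 0.30, FDR = 0.00804). So were the incretin receptor gene Gipr (-1.98, FDR = 0.00865), the calcium-binding protein gene Casq1 (-1.77, FDR = 0.0161) and Hif3a (-1.68, FDR = 0.0361). Cd36 itself differed by -1.46 (SE 0.14, FDR = 0.00804). Outside the cell cycle, nuclear-encoded oxidative phosphorylation (median 0.28, camera FDR = 7.25e-06), macrophage (0.27, FDR = 0.0207) and extracellular matrix lists (0.16, FDR = 0.0128) were higher in CD36KO. PPAR target (-0.34, FDR = 0.00189), atrial (-0.51, FDR = 0.0128), hypoxia (-0.34, FDR = 0.0315) and skeletal muscle lists (-1.80, FDR = 0.0409) were lower, the last with 1494 FPKM summed in CD36CKO 3 alone. With an estimated correlation the adjusted p of each was 0.807, and none of these lists passed by fry. Without CD36CKO 3 the skeletal muscle median was -0.00131 (FDR = 0.810). Single libraries also ended the atrial (FDR = 0.139 without CD36CKO 1), macrophage (0.0773 without CD36CKO 1), hypoxia (0.0591 without CD36CKO 1), extracellular matrix (0.0786 without CD36CKO 1) and ribosomal calls (0.183 without CD36CKO 2). Oxidative phosphorylation was at 0.11 with quantile normalization and 0.14 with mitochondrial and haemoglobin genes removed, the extracellular matrix list at 0.03 with those genes removed and not past the threshold with quantile normalization (0.0696), and macrophage genes at 0.44 without CD36CKO 3. Atrial genes were at -0.82 without CD36KO 2 and -0.30 without CD36KO 3, hypoxia genes at -0.22 without CD36KO 3, and PPAR targets at -0.14 with no filter. The ribosomal protein list was higher at 0.13 (camera FDR = 0.0314; adjusted p = 0.840 with an estimated correlation) but at -0.05 with quantile normalization and -0.01 with mitochondrial and haemoglobin genes removed, where the median of all genes moved to -0.12. Their members past the threshold were also Cox8b (1.40), also Atp5k (1.10), also Ndufa1 (0.72), also Rps27 (0.91), also Fbn1 (0.59) and also Col15a1 (0.82), higher, and also Slc25a42 (-0.85), also Mt2 (-1.30) and also Ddit4 (-1.15), lower. The study's axis was at 0.22 (FDR = 0.560). In all 318 genes were higher and 235 lower in CD36KO (128 and 156 with mitochondrial and haemoglobin genes removed), 553 genes, and 10 lists passed camera, 0 with an estimated correlation (smallest adjusted p = 0.722) and 3 by fry. Without the 2 libraries with Y-linked expression 48 genes passed, without CD36CKO 3, which held skeletal muscle transcripts, 311, and without CD36KO 3 alone 29. Fitted with only the libraries of the groups compared, more genes passed here than in either contrast with WT. The order of the counts of these contrasts therefore depends on whether the spread of WT is pooled.

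Taken against WT as the mean of both knockouts, which gives 6 libraries against 3, the largest rises included mt-Co3 (2.06, FDR = 0.0270), Ucp3 (1.72) and Fbp2 (1.68). The largest falls were in the atrial transcripts Myl7 (-4.27), Myl4 (-3.54) and Mybphl (-3.23) and in Uts2b (-2.92). Cd36 was at -0.41 (FDR = 0.0543), an average over a group in which it fell and a group in which it did not. Of 60 G2/M genes 55 fell (59 adjusted over the list alone; median -1.06; camera FDR = 4.58e-33; adjusted p = 0.314 with an estimated correlation). In this contrast 863 genes were higher and 1079 lower (1435 and 452 with mitochondrial and haemoglobin genes removed), and any genotype gave 2125 genes. Lists past camera numbered 14, with 0 under an estimated correlation and 13 by fry. With the atrial score as a covariate limma called 1 gene, with 849 at an unadjusted p under 0.05, and without the 2 libraries with Y-linked expression 654.

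The WT contrasts shared 598 genes in the same direction, 244 higher and 354 lower in both, and 5 genes passed in opposite directions. Unchanged groups simulated against the same WT libraries shared 0.02 genes on average over 50 draws, and independent lists of these sizes would share 38.0 higher and 59.8 lower. Neither value gauges the overlap of these lists. Unchanged groups have almost no calls to share, and independent lists leave out that both contrasts use the same WT libraries. Log2 fold changes correlated across genes at 0.637, against 0.499 in the simulation, and their covariance was 0.103 against 0.0174, where genes are not independent replicates. The same sign was found for 74.4% of tested genes, against 66.6% simulated. A simulated correlation of 0.499 is what groups of equal spread give. In the data the median SD of a gene was 0.21 in WT, 0.11 in CD36KO and 0.14 in the libraries labelled CD36CKO. Wider spread in the shared WT libraries raises the correlation, the covariance and the share of the same sign without any effect of genotype. The simulated values may thus be too low. The 3 WT libraries cannot be divided into separate sets of at least 2. Part of the excess may therefore come from the shared controls, and in the correlation and the sign all of it.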

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

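The comparisons with other groupings of the libraries and the tests of explanations in this part were chosen after the results were seen, while the test of the difference between knockouts was fixed before. The results below drew attention because the effect in CD36KO and the effect in the libraries labelled CD36CKO differed, as tested with limma on the difference itself (adjusted p). In all, 553 genes differed between CD36KO and the libraries labelled CD36CKO, whose Cd36 level over the whole gene in the whole heart does not bear out their label. Cd36 was at -1.46 (log2, CD36KO minus CD36CKO, here and below). Cell-cycle genes were higher in CD36KO: Cdc20 1.17, Ube2c 1.14, Cdca3 1.21, Tacc3 0.83, Kif4 1.28, Pbk 1.90, Mcm2 0.95, Mcm4 0.77, Rrm1 0.82, Rrm2 1.49, Tk1 0.98, Ccnd1 0.74 and Cdkn2c 1.04. Also higher were Apln 2.20, Atf3 1.97, Rps27a 1.72, Scgb1c1 1.30, Atp5k 1.10, Aldh1a2 1.0 and Mthfd2 0.53. Lower in CD36KO were Myh7 -2.67, Gipr -1.98, Casq1 -1.77, Hif3a -1.68, Dpep1 -1.46, Cnn1 -1.33, Mt2 -1.30, Tmem82 -1.22, Ddit4 -1.15, Gadd45b -1.02, Slc25a42 -0.85, Hey2 -0.80, Kcnj2 -0.75, Krt19 -0.65, Erbb2 -0.47 and Rarg -0.43. As lists, by their median, G1/S genes (0.74), G2/M genes (0.98), nuclear-encoded oxidative phosphorylation (0.28), macrophage (0.27), ribosomal protein (0.13) and extracellular matrix genes (0.16) were higher, and PPAR targets (-0.34), atrial (-0.51), hypoxia (-0.34) and skeletal muscle genes (-1.80) lower. Without CD36CKO 3 the skeletal muscle median was -0.00131 (adjusted p = 0.810), and the atrial, macrophage, hypoxia, ribosomal and extracellular matrix calls were each lost without some single library. With an estimated correlation the list adjusted p were 0.722 or higher.

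Other groupings of the same libraries were fitted in the same way. For CD36KO against WT (1527 genes), for the libraries labelled CD36CKO against WT (1547) and for CD36KO against those libraries (553) the 10 possible groupings are too few to judge, with at most 1, 0 and 1 genes in any other. For both knockouts against WT the real grouping gave 1942 genes and was 1 of 84 with as many, where the highest other gave 230, which argues against chance. For any genotype it gave 2125 genes and was 1 of 100 drawn, where the highest other gave 126, which also argues against chance.

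G2/M genes fell in the libraries labelled CD36CKO by a median of -1.52. A length bias of the libraries could give this, but with the length trend removed 58 of the 60 genes still fell, which argues against it. A smaller share of cells other than cardiomyocytes could also give it. The endothelial median was -0.0298, with members past the threshold in both directions, and the mural one 0.31, which argues against a general loss of these cells. The macrophage (-0.27), fibroblast (-0.36), epicardial (-0.66) and endocardial medians (-0.79) were lower, so fewer cells of those types remain open. Levels of such markers do not show how many cells divide, so less division among any of these cells remains open too. Without the 2 libraries with Y-linked expression 51 genes still fell, which argues against these libraries as the source. Genotype, age in hours and litter remain open as biological explanations and were not tested.

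Atrial genes were lower in CD36KO (median -1.84) and in the libraries labelled CD36CKO (-1.41). A varying share of atrial tissue cannot be told apart from shared regulation here. The mean correlation of the list within groups was 0.57, which both would give, and G2/M genes (0.72) and oxidative phosphorylation genes (0.86) varied together more closely, so an effect of genotype stays open too. Mitochondrial and haemoglobin genes were also removed and the libraries rescaled to the same FPKM sum. The median was then still -1.76 in CD36KO and -1.18 in the libraries labelled CD36CKO. These values argue against scaling by those reads as the source of the fall, though the setting changes the scaling as well.

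Calls shared by both knockouts were frequent on chromosome 5 at positions above that of Cd36. Within 10 Mb of the gene, a window set after the values were seen, 9 of 68 tested genes (13.2%) were shared calls, against 589 of 12137 elsewhere (4.85%; Fisher exact p = 0.00570), as DNA of another strain kept around a targeted gene could give. All 9 lay above Cd36, with starts from 18470133 (Gnai1) to 25426902 (Galnt11). None of the tested genes of the window below Cd36 was a shared call. They were far fewer than the tested genes above it, so it cannot be told whether the calls are centred on the gene. Of 259 other windows of this width 0.772% had as high a share. As the window was set after the calls in it were seen, this share and the Fisher p describe it and cannot exclude chance. The strains are not given in the sources used here, and an effect of the edited locus on its neighbours could give the same values and was not tested.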

How the results depend on the processing

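The atrial covariate, the length trend, voom and the fit without the 2 libraries with Y-linked expression were chosen after seeing the data, and so was the gene-by-gene method of library weights, since the default did not converge. Of 3635 alternative values of named genes 2967 kept direction and call, 604 lost the call, 50 gained it and 14 reversed. Of 141 named-gene results past the threshold, 75 stayed past it without each library in turn. The cause of the changes below was not tested, except that fewer libraries or genes leave less to test. Depth sets a floor of 0.128 to 0.192 FPKM for a transcript of 1000 bases. Where a group kept 2 libraries, the pooled spread of limma was used.

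Counts are given for CD36KO against WT, the libraries labelled CD36CKO against WT, CD36KO against these, both knockouts against WT, any genotype and the overlap (1527, 1547, 553, 1942, 2125 and 598 genes), and counts within 1.5 times are left out. No filter gave 743, 753, 169, 949, 1038 and 247. A mean of at least 5 FPKM gave 1000 (labelled CD36CKO), 338 (between knockouts) and 1355 (any). Mitochondrial and haemoglobin genes removed gave 941 (CD36KO) and 284 (between knockouts). Library weights gave 5811, 4804, 1944, 6350, 7205 and 2897, but WT 1 had a weight of 7.78 against 0.435 and 0.176 for WT 2 and WT 3, so these counts rest in effect on 1 WT library. The atrial covariate gave 0, 13, 14, 1, 173 and 0 in limma, with 751, 1342, 1978 and 849 at an unadjusted p under 0.05 in the 4 contrasts; it is the mean of the atrial list, so it removes that list's change by construction and overlaps with genotype. Without the libraries with Y-linked expression there were 200, 412, 48, 654, 448 and 82. Only the libraries compared gave 838, 504 and 1364, so the contrast between knockouts, with the fewest calls in the single fit, then had the most. The single fit pools the spread of all groups, also in the contrast without WT. The median SD of a gene was 0.21 in WT, 0.11 in CD36KO and 0.14 in the libraries labelled CD36CKO. An absolute log2 fold change of at least 1 gave 193, 259, 131 and 186, and an adjusted p of 0.1 gave 2624, 2846, 1191, 3314, 3755 and 1221.

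Same-numbered libraries correlated from -0.433 to 0.141, and 8 of 18 best matches had the library's own number, so the numbers do not pair the libraries. With the replicate number as a block the counts were 1004, 963, 399, 1350, 1412 and 358.

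Leave-one-out counts ranged 405 to 3203 (CD36KO), 330 to 3950 (labelled CD36CKO), 29 to 1463 (between knockouts), 759 to 4099 (both), 811 to 4889 (any) and 167 to 1882 (overlap). Single libraries moved them by over 1.5 times, in the same order. Without WT 1: 732, 800, both 969, any 1077, overlap 296. Without WT 2: 809, 585, both 759, any 1281, overlap 211. Without WT 3: 3203, 3950, 1463, 4099, 4889, 1882. Without CD36KO 1: 405, 1008, 186, 1029, 916, 192. Without CD36KO 2: 596, 995, 159, 1157, 1008, 258. Without CD36KO 3: 405, 937, 29, 1003, 814, 205. Without CD36CKO 1: labelled CD36CKO 707, between knockouts 351, both 1272, overlap 299. Without CD36CKO 2: 1009, 330, 62, 979, 811, 167. Without CD36CKO 3: labelled CD36CKO 947, between knockouts 311, overlap 367.

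Lists past the threshold numbered 12, 15, 10 and 14 in the 4 contrasts, 0 in each with an estimated correlation, 3 by fry between knockouts and 9 for both knockouts with the atrial covariate; leave-one-out gave 12 to 18, 10 to 18, 6 to 11 and 13 to 16, with 6 between knockouts without CD36CKO 1. With an estimated correlation the medians stayed at 0.45 (G1/S) and -0.60 (G2/M) in CD36KO, -1.52 (G2/M) in the libraries labelled CD36CKO, and 0.74 and 0.98 between knockouts, none past the threshold. G1/S in the libraries labelled CD36CKO lost its call with a mean of at least 5 FPKM (-0.32), library weights (-0.24), an estimated correlation (-0.28) and fry (-0.28); leave-one-out gave -0.36 to -0.21.

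Reversed list medians in CD36KO were fatty acid uptake with library weights (-0.0350) and the atrial covariate (-0.0230). In the libraries labelled CD36CKO they were the study's axis (0.18) and extracellular matrix (0.00628) with mitochondrial and haemoglobin genes removed, oxidative phosphorylation with quantile normalization (0.0564), and uptake (-0.00965) and atrial genes (0.0459) with the atrial covariate. Between knockouts cell-cycle brakes reversed with no filter (0.0307), at least 5 FPKM (0.0378), the length trend (0.00575), without CD36KO 2 and without CD36CKO 2 (leave-one-out -0.0805 to 0.0688). Retinoid genes reversed with at least 5 FPKM (0.00865). Fatty acid uptake reversed with quantile normalization (-0.00592), mitochondrial and haemoglobin genes removed (-0.11), without Y-linked libraries (-0.0133), without CD36CKO 2 (-0.00126) and CD36CKO 3 (-0.00492; leave-one-out up to 0.0922). Fatty acid oxidation reversed with median-ratio scaling (-0.000138), quantile normalization (-0.12), those genes removed (-0.13), library weights (-0.00574), the length trend (-0.0270), and without CD36KO 2, CD36CKO 2 or CD36CKO 3 (leave-one-out -0.0753 to 0.0546). Ribosomal proteins reversed with quantile normalization (-0.0506) and those genes removed (-0.00550).

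Reversed genes with the atrial covariate were Myl7 (1.76), Sln (1.35), Fabp5 (0.0237) and Rxra (-0.0522) in CD36KO, and Myl7 (1.05) and Mybphl (1.40) for both knockouts. In the libraries labelled CD36CKO, Ppard (0.23), Rxrb (0.11) and Rxra (0.18) reversed with mitochondrial and haemoglobin genes removed, Ppard with library weights (0.0470) and without WT 3 or CD36CKO 1 (leave-one-out -0.14 to 0.10), and Rxrg without Y-linked libraries (-0.0519) and without CD36CKO 3 (leave-one-out -0.0519 to 0.54).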

Other observations

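The genes named in this part were chosen after their values were seen. Igkc, the constant region of the kappa immunoglobulin light chain, was at 0.364 ± 0.139 FPKM in WT, 4.11 ± 0.650 in CD36KO and 0.863 ± 0.611 in the libraries labelled CD36CKO (SD, n = 3), a log2 fold change of 1.90 in CD36KO (SE 0.23, adjusted p = 0.00283 from limma) and 0.40 in the libraries labelled CD36CKO (adjusted p = 0.247), with a difference of 1.5 (adjusted p = 0.0108). Ighm, the heavy chain of IgM, was at 1.34 (SE 0.20, adjusted p = 0.00661) and 0.21 (adjusted p = 0.504), with a difference of 1.13 (adjusted p = 0.0178). The gene with the smallest p in both WT contrasts was AI506816, a long noncoding RNA on chromosome 5, at 13.3 ± 0.962 FPKM in WT, 0.988 ± 0.124 in CD36KO and 0.743 ± 0.290 in the libraries labelled CD36CKO (-2.85, adjusted p = 2.25e-05, and -3.05, adjusted p = 1.17e-05). Prkag2os1, antisense to Prkag2 on the same chromosome, fell by a log2 fold change of -1.78 and -1.53 (adjusted p = 0.00219 and 0.00195). AI506816 and Prkag2os1 are among the shared calls of the window around Cd36 described above. DNA of another strain kept there could give their falls too, which was not tested. Myh6, the adult alpha-myosin heavy chain, was at -0.58 (adjusted p = 0.0560) and -0.45 (adjusted p = 0.109).

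Gapdh, often used as a reference gene, was at 118, 119 and 128 FPKM in WT 1 to 3, at 6.20, 2.36 and 65.8 in CD36KO and at 97.2, 14.9 and 65.3 in the libraries labelled CD36CKO; it has many processed pseudogenes and overlaps Iffo1, so these values are uncertain. Of 511 processed pseudogenes tested, 8 were higher and 40 lower in CD36KO, and 8 and 42 in the libraries labelled CD36CKO. Of 574 long noncoding RNAs 38 were higher and 36 lower in CD36KO, and 34 and 33 in the libraries labelled CD36CKO. In CD36CKO 3 the fast skeletal muscle transcripts Mylpf, Tnnt3, Tnni2 and Myh8 were at 685, 314, 238 and 99.9 FPKM and Acta1 at 1813 FPKM, against 17.8 to 111 FPKM of Acta1 in the other 8 libraries.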
